A study of Danio rerio with 6 samples.

How the data were processed

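The series holds 6 RNA-seq libraries of Tg(fli1:EGFP) zebrafish cells in 3 populations, Fli1-, Low-Fli1+ and High-Fli1+, with 2 libraries each. Per the labels, 100 ng of total RNA was poly-A enriched and reverse transcribed to double-stranded cDNA for each library. The labels state that each sample was run in duplicate, without saying what a duplicate shares with the others of its number. The deposited values are FPKM per gene and library, which the authors made before depositing the table; the aligner, software versions, genome build and annotation are not stated. The file header names the unit, and the values, which are not whole numbers and have unequal column sums, are neither counts nor TPM.

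The table has 29144 entries with gene names and no identifiers or coordinates. Of them 18 are named by a calendar date, as happens when a spreadsheet converts a gene name, and 2 dates are each held by more than 1 entry. These were left out; they held between 0.0655% and 0.149% of the FPKM sum of a library. The remaining 29126 gene names were matched to a reference annotation by name alone, and 24595 of them (84.4%) were found there. Some genes appear under another name: prdm16 as PRDM16, ldb1b as LDB1, plvapb as vsg1 and hbbe1.3 as si:ch211-5k11.12. Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, which kept 19237 and removed 9889.

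Sequencing depth cannot be read from FPKM, so no counting error can be given for single values. The FPKM that 1 fragment is worth was estimated for each library relative to Fli1- replicate 1, as 1.01 for Fli1- replicate 2, 1.39 and 0.979 for Low-Fli1+ and 1.01 and 1.47 for High-Fli1+. It is the most common ratio of the 2 values over genes above 0 and under 2 FPKM in both libraries. The estimate is rough, since transcript length and effective length enter it. Genes of equal expression also give a ratio near 1 at any depth, so it is no measure of depth. The 5th percentile of values above 0 was 0.281 and 0.277 FPKM in Fli1-, 0.915 and 0.660 in Low-Fli1+ and 0.330 and 0.267 in High-Fli1+ libraries.

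Values were taken as log2(FPKM + 1) without further scaling. All 6 libraries entered 1 linear model by population in limma 3.58.1 under R 4.3.3, with moderated variances that follow a trend with level (3 residual and 2.89 prior degrees of freedom). Populations were compared by moderated t tests, and over all 3 by the moderated F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With 2 libraries per population, no exact or permutation test can reach that threshold. Every adjusted p for a gene is from limma.

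Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 72 tests (24 lists and 3 comparisons). Camera with the correlation estimated from the data, and fry, were run as checks. The lists named 705 genes, of which 691 were found, 10 of them by a synonym. Some genes stand in more than 1 list, for example gata1a, tal1, lmo2, vegfaa, vegfc, notch1a, notch3 and twist1a. Counts adjusted over the list alone use the members' p-values from the same model. A comparison with an estimated correlation keeps the correlation that the list's members show across residuals, which with 3 residual degrees of freedom is itself poorly known.

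Genes named in the text were chosen by a fixed rule. In each comparison these are the 10 higher and 10 lower called genes with the largest fold changes, both libraries of 1 population above both of the other, a mean of at least 5 FPKM in the higher population and no provisional name. To these come fli1a, fli1b, lmo2 and prdm16, the called members of each list with the 4 largest fold changes, and up to 10 genes highest in Low-Fli1+. A gene that the rule names is left out of the text because it is withheld for evaluation. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from 1 added alternative, the tests that the closing section names, and the genes and the check that the text says were added later.

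Each comparison was repeated with pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 2, quantile normalization, median-ratio scaling, no variance trend, only the populations compared, the replicate number as a block, array weights, and without each library in turn. The added alternative leaves out 1810 genes at 0 in 1 library of a population and at 5 FPKM or more in the other. The overlap of the comparisons against Fli1- was set beside 20 simulations of unchanged groups against the same Fli1- libraries. The correlation of fold changes was also computed with 1 Fli1- library for each comparison, a check added after the data were seen.

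The procedure was tested on simulated data with 200 changed genes of 19237. It recovered 0% of genes changed 2-fold or 4-fold, and 53.5%, 50.5% and 47% of those changed 16-fold in High-Fli1+ against Fli1-, Low-Fli1+ against Fli1- and High-Fli1+ against Low-Fli1+, with 9, 3 and 3 unchanged genes called. These shares do not carry over to the data, where 3316, 622 and 1033 genes were called and the adjustment is less strict. Changes under 4-fold were called there, such as PRDM16 between the positive populations (log2 fold change 1.64). Of simulated lists, 2 of 2 tests of a list shifted by 1 on the log2 scale were called, and 0 of 70 others. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.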

Results

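Gene expression was measured by RNA sequencing in cells of Tg(fli1:EGFP) zebrafish, a line in which regulatory sequence of fli1a drives a green fluorescent reporter in blood vessels, some blood cells and the pharyngeal arches. The 6 libraries fall into 3 populations of 2 libraries each, which the labels name Fli1-, Low-Fli1+ and High-Fli1+. The series title places the study in angiogenesis and names an LMO2-PRDM16 axis, so the comparisons ask which genes mark each reporter population and where lmo2 and prdm16 stand among them. The labels give neither a developmental stage nor how the populations were separated, and they do not say that replicates come from separate embryos or separate sorts. The p-values therefore measure the spread between these libraries.

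The values are FPKM, so the number of sequenced fragments per library is unknown. FPKM summed to 550433 and 608974 in the Fli1- libraries, to 430723 and 541663 in the Low-Fli1+ libraries, and to 448789 and 712585 in the High-Fli1+ libraries. A single non-coding RNA, Metazoa_SRP, held 27.4% of the sum in High-Fli1+ replicate 2 and 1.77% in Low-Fli1+ replicate 1, the highest and lowest shares of the 6. The Low-Fli1+ libraries had the most genes listed at 0, with 14082 and 12575 of 29126. The Fli1- libraries had 8683 and 8451 such genes, and the High-Fli1+ libraries 11054 and 11457. Across genes, which are not independent replicates, Pearson's r between the 2 libraries of a population was 0.927 in Fli1-, 0.892 in High-Fli1+ and 0.737 in Low-Fli1+. Low-Fli1+ replicate 2 had r of 0.752 with Fli1- replicate 2 and 0.747 and 0.748 with the High-Fli1+ libraries, above that with its pair. With Fli1- replicate 1 it was 0.729. Low-Fli1+ replicate 1 had its highest r with its pair. The first principal component held 44.4% of the variance and ordered the populations as Fli1-, Low-Fli1+ and High-Fli1+. The Low-Fli1+ libraries lay apart from each other on the second, which held 25.7%.

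**Figure D1:**
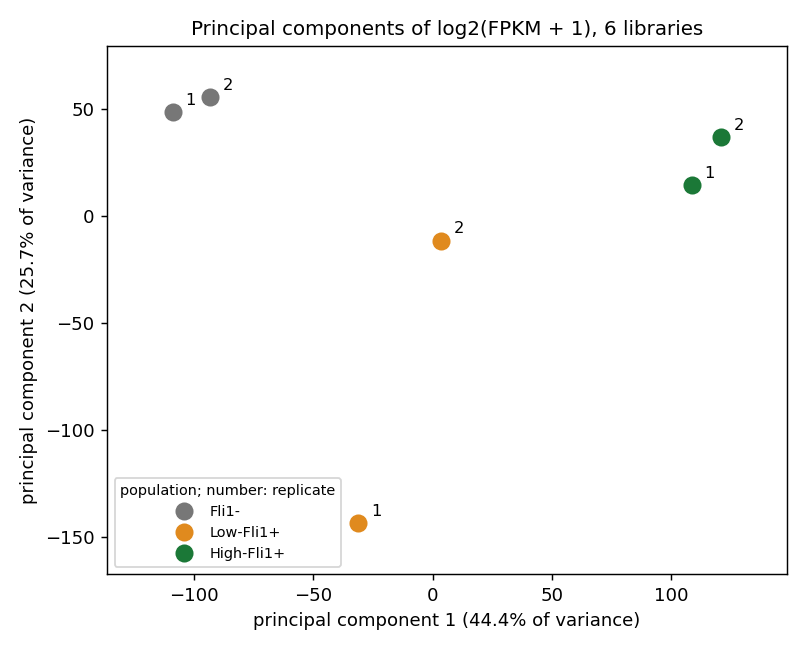
Each point is 1 of the 6 libraries on the first (x axis, 44.4% of variance) and second (y axis, 25.7%) principal components of log2(FPKM + 1), coloured by population and marked with its replicate number. The Low-Fli1+ pair lies between the other populations on the x axis, and Low-Fli1+ replicate 1 is the lowest point on the y axis.

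Prdm16, listed as PRDM16 and encoding a zinc-finger transcriptional regulator, rose with reporter level, while lmo2, which encodes an adaptor of blood and endothelial transcription complexes, was not called in any comparison. PRDM16 stood at 18.7 ± 2.37 FPKM in Fli1-, 41.6 ± 0.511 in Low-Fli1+ and 131 ± 8.81 in High-Fli1+ cells (mean ± SD, n = 2 in each), a 6.73-fold difference between the extremes on the log2(FPKM + 1) scale used for all fold changes here. It was higher in High-Fli1+ than in Fli1- cells (log2 fold change 2.75 ± 0.22 (SE), adjusted p = 0.00306) and than in Low-Fli1+ cells (log2 fold change 1.64 ± 0.22 (SE), adjusted p = 0.0236). Low-Fli1+ against Fli1- gave a log2 fold change of 1.12 (adjusted p = 0.0603). The lmo2 values were 13 and 10.7 FPKM in Fli1-, 0 and 4.28 in Low-Fli1+ and 3.17 and 1.17 in High-Fli1+ libraries, a log2 fold change of -2.08 ± 0.88 (SE) in High-Fli1+ against Fli1- (adjusted p = 0.170) and of -2.48 in Low-Fli1+ against Fli1- (adjusted p = 0.187). High-Fli1+ against Low-Fli1+ gave 0.39 for lmo2 (adjusted p = 0.829), and the sign turned without Low-Fli1+ replicate 1 (-0.81) or High-Fli1+ replicate 1 (-0.080), while leaving out Low-Fli1+ replicate 2 gave 1.59. In Low-Fli1+ against Fli1- lmo2 was at -1.28 without Low-Fli1+ replicate 1 (adjusted p = 0.228) and at -3.68 without replicate 2 (0.0537). The call of PRDM16 between the reporter-positive populations was lost without Fli1- replicate 1 (adjusted p = 0.138), Fli1- replicate 2 (0.139), Low-Fli1+ replicate 1 (0.0555), High-Fli1+ replicate 1 (0.102) or High-Fli1+ replicate 2 (0.111). Between High-Fli1+ and Fli1- it was kept under every setting run. For lmo2 in High-Fli1+ against Fli1-, leaving out Low-Fli1+ replicate 1 (adjusted p = 0.0411) or replicate 2 (0.0444) made it a call.

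The reporter's own gene, fli1a, an ETS-family transcription factor of endothelial and blood cells, followed the labels. It stood at 3.30 ± 3.19 FPKM in Fli1-, 59.4 ± 10.5 in Low-Fli1+ and 217 ± 34.9 in High-Fli1+ cells (mean ± SD, n = 2). It was higher in High-Fli1+ (log2 fold change 5.89 ± 0.55 (SE), adjusted p = 0.00381) and in Low-Fli1+ (log2 fold change 4.03 ± 0.55 (SE), adjusted p = 0.0305) than in Fli1- cells, and the log2 fold change of 1.85 between the positive populations did not pass (adjusted p = 0.113). Its paralog fli1b stood at 0 and 0.245 FPKM in Fli1-, 21.4 and 8.25 in Low-Fli1+ and 7.56 and 8.95 in High-Fli1+ libraries, higher in High-Fli1+ (adjusted p = 0.0220) and in Low-Fli1+ (adjusted p = 0.0384) than in Fli1- cells. High-Fli1+ against Low-Fli1+ gave -0.64 for fli1b (adjusted p = 0.544), -0.0040 without Low-Fli1+ replicate 1 and -1.28 without Low-Fli1+ replicate 2 (adjusted p = 0.115). The fli1a call in High-Fli1+ was lost without High-Fli1+ replicate 1 (adjusted p = 0.0567) or replicate 2 (0.0612), and that in Low-Fli1+ without Low-Fli1+ replicate 1 (0.0768), Low-Fli1+ replicate 2 (0.0593), High-Fli1+ replicate 1 (0.101) or High-Fli1+ replicate 2 (0.102). The fli1b call in High-Fli1+ was lost without Fli1- replicate 1 (0.172), Fli1- replicate 2 (0.140), High-Fli1+ replicate 1 (0.115) or High-Fli1+ replicate 2 (0.137). In Low-Fli1+ it was lost without Fli1- replicate 1 (0.200), Fli1- replicate 2 (0.170), Low-Fli1+ replicate 1 (0.0615), High-Fli1+ replicate 1 (0.106) or High-Fli1+ replicate 2 (0.106).

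**Figure D2:**
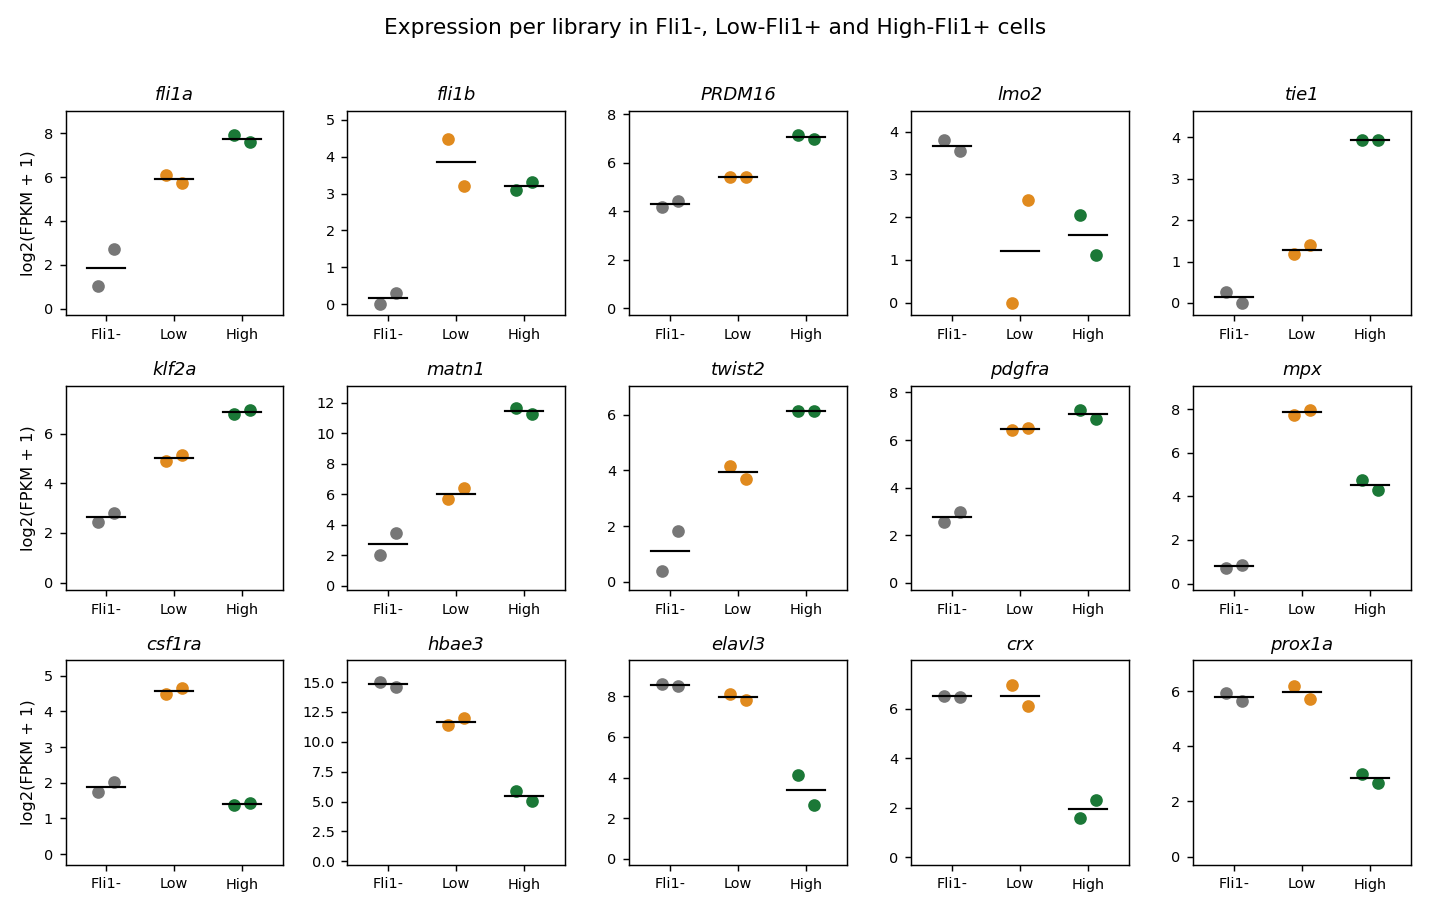
Each panel shows log2(FPKM + 1) of 1 gene (y axis) in the 2 libraries of each population (x axis), with a line at the population's mean. From Fli1- to High-Fli1+, PRDM16 and fli1a are higher, hbae3 and elavl3 are lower, and mpx is highest in Low-Fli1+, at 214 and 251 FPKM.

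The genes of the Lmo2-Prdm16 axis and its partners went both ways between High-Fli1+ and Fli1- cells. Of 16 tested, 3 were higher and 5 lower (6 and 6 adjusted over the list alone). Medians of lists are of log2 fold changes. Besides PRDM16, mecom, a close relative of prdm16 and a blood stem cell regulator, was higher (log2 fold change 3.57 ± 0.34 (SE), adjusted p = 0.00381). So was tcf12, an E-protein partner of Tal1 (log2 fold change 1.60). The lower members were gata1a, the red cell regulator (-2.54), tal1, the blood and endothelial partner of Lmo2 (-1.88), the LIM-domain binders ldb1a (-1.44) and LDB1 (-1.64), and ssbp3b (-1.83). Here tcf12, the LIM-domain binders and ssbp3b lie outside the rule for naming genes and were added after their values were seen. The list's test gave no call (adjusted p = 0.437), and its direction was higher while its median was -0.48 and its mean -0.04. In Low-Fli1+ against Fli1- cells, mecom (1.96) and tcf12 (1.41) were higher. By limma 2 were higher and 0 lower, against 3 higher and 2 lower adjusted over the list alone and 3 lower at an unadjusted p under 0.05. That list test was also not called (adjusted p = 0.570), with a median of 0.01 that became -0.03 under median-ratio scaling, a mean of -0.11 and a test direction of higher. In High-Fli1+ against Low-Fli1+, PRDM16 was the member called higher and 0 were lower, against 2 and 1 adjusted over the list alone and 3 lower at an unadjusted p under 0.05 (median 0.09, adjusted p = 0.480). The calls of mecom, gata1a and tal1, and that of tcf12 in Low-Fli1+, were each lost without at least 1 library.

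High-Fli1+ cells held cartilage matrix, pharyngeal arch and endothelial transcripts at far higher levels than Fli1- cells, and red cell and neuronal transcripts at far lower ones. Among genes with a name of their own, the largest rise was in matn1, a cartilage matrix protein, at 3.06 and 10.1 FPKM in Fli1- and 2823 ± 553 (SD, n = 2) in High-Fli1+. That is 416-fold (log2 fold change 8.70 ± 0.52 (SE), adjusted p = 0.00235). It was followed by emilin3a, an extracellular matrix glycoprotein, at 0 and 1.36 FPKM in Fli1- and 573 and 586 in High-Fli1+ libraries, and by fgfbp2b, a growth factor binding protein (304-fold). Also among the 10 largest rises were the aggrecans acana (172-fold) and acanb (79.6-fold), the collagens col11a2 (113-fold), col8a2 (111-fold), col9a1a (100.2-fold) and col2a1a (77.8-fold), and the tenascin tnxba, at 0 and 0.776 FPKM in Fli1- and 146 and 121 in High-Fli1+ libraries. Among the same genes, the largest fall was in the embryonic globin hbbe1.1, from 4037 ± 33.9 to 4.0 ± 4.96 FPKM (log2 fold change -10.14 ± 1.02 (SE), adjusted p = 0.00423). The other large falls were in the globins hbae3, hbbe2, hbbe1.2 and hbbe3, the red cell carbonic anhydrase cahz (223-fold), the heme synthesis enzyme alas2 (120.4-fold) and the cone transducin subunit gnb3a (59.5-fold). In both High-Fli1+ libraries hbbe3, insulin (ins) and the galectin lgals2b were listed at 0, against 164 and 219.8, 116 and 211, and 87.2 and 64.4 FPKM in Fli1- libraries. Globin copies are near-identical, so the split between them is uncertain.

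In this comparison limma called 3316 of 19237 genes, 1113 higher and 2203 lower in High-Fli1+. The share of higher calls was 33.6%, and it was 49.2% under quantile normalization, which moved the median log2 fold change of all genes from -0.35 to 0.01 (to -0.10 under median-ratio scaling). The count was 836 without Fli1- replicate 1, 956 without Fli1- replicate 2, 548 without High-Fli1+ replicate 1, 201 without High-Fli1+ replicate 2, and 5659 with array weights. Of the 98 called genes named by the rule, 35, 41, 44 and 27 remained called without those 4 libraries in turn, and 96 and 97 without Low-Fli1+ replicates 1 and 2. The 20 called whichever library was left out include PRDM16, matn1, acana, col9a1a, col11a2, col2a1a, alas2, cahz, hbbe2 and lgals2b.

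Endothelial transcripts were higher in High-Fli1+ than in Fli1- cells as a group. Of 29 endothelial core genes, 17 were higher and 0 lower (22 and 0 adjusted over the list alone) (median 2.67, adjusted p = 4.89e-16, adjusted p = 0.0780 with an estimated correlation). They include egfl7, a secreted vessel factor, at 0 and 0.267 FPKM in Fli1- and 24.5 and 32.0 in High-Fli1+ libraries, and tie1, an endothelial receptor kinase, at 0.208 and 0 against 14.3 and 14.3. The adhesion molecule pecam1 was listed at 0 in both Fli1- libraries and stood at 11.3 and 13 in High-Fli1+. Angiogenic signalling genes had 8 higher and 1 lower (13 and 1 adjusted over the list alone) of 30 (median 1.06, adjusted p = 1.74e-06, adjusted p = 0.0780 with an estimated correlation). They were led by the flow-responsive factors klf2a (log2 fold change 4.22) and klf2b (3.93), the chemokine cxcl12b (3.37) and the BMP receptor acvrl1 (3.29). Arterial and Notch genes went both ways, 6 higher and 2 lower (7 and 5 adjusted over the list alone) of 22 (median 0.94, adjusted p = 0.00589, adjusted p = 0.174 with an estimated correlation). They include notch2 (2.91), her6 (2.71) and hey1 (2.53) higher and the water channel aqp1a.1 (-2.40) lower. Venous and lymphatic genes had 5 higher and 1 lower (8 and 1 adjusted over the list alone) of 18 (median 1.39, adjusted p = 1.45e-05, adjusted p = 0.0831 with an estimated correlation). The VEGF receptor flt4 (3.21), the ephrin receptor ephb4b (2.47) and stab2, at 0.170 and 0.310 against 4.64 and 5.16 FPKM, were higher, while prox1a, a lymphatic factor that also acts in retina and liver, was lower (-2.96). Among these genes klf2a, klf2b and notch2 were called whichever library was left out. Each of the others lost its call without at least 1 library.

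Skeletal, pharyngeal and connective tissue genes were also higher in High-Fli1+ than in Fli1- cells. Of 23 cartilage and bone genes, 20 were higher and 0 lower (22 and 0 adjusted over the list alone) (median 5.38, adjusted p = 6.16e-28, adjusted p = 0.0780 with an estimated correlation), led by matn1, acana, col11a2 and col9a1a. Neural crest and pharyngeal arch genes had 17 higher and 2 lower (20 and 2 adjusted over the list alone) of 29 (median 2.93, adjusted p = 1.25e-12, adjusted p = 0.0780 with an estimated correlation). Their largest changes were in transcription factors of arch mesenchyme, prrx1b (5.23), twist2 (5.02), gsc (4.66) and dlx4a, the last at 1.5 and 0 against 39.1 and 52.7 FPKM. Mural and fibroblast-like genes had 22 higher and 1 lower (25 and 2 adjusted over the list alone) of 32 (median 3.16, adjusted p = 2.08e-19, adjusted p = 0.140 with an estimated correlation). The largest were foxc1b (5.47), foxc1a (4.28), the pericyte proteoglycan cspg4 (4.69) and the growth factor receptor pdgfra (4.31). Basement membrane and matrix remodelling genes had 20 higher and 1 lower (22 and 1 adjusted over the list alone) of 32 (median 2.31, adjusted p = 5.58e-17, adjusted p = 0.149 with an estimated correlation). They include the collagen crosslinker loxl2b (4.26), the collagen chaperone serpinh1b (4.14) and the matrix proteases mmp14a (4.02) and mmp2 (3.86). Of the genes named in this group, matn1, acana, col11a2, col9a1a, cspg4, foxc1b and pdgfra were called whichever library was left out. The others each lost the call without at least 1 library.

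Blood lineages moved in different directions. Of 20 erythroid genes, 0 were higher and 18 lower (0 and 19 adjusted over the list alone) (median -5.73, adjusted p = 5.40e-13, adjusted p = 0.0780 with an estimated correlation). Among them hbae3 went from 28789 ± 5903 to 45.3 ± 17.8 FPKM, with si:ch211-5k11.12, a globin locus, hbbe1.1 and hbbe2 the other large falls. Myeloid genes had 10 higher and 0 lower (13 and 1 adjusted over the list alone) of 25 (median 1.40, adjusted p = 1.30e-07, adjusted p = 0.218 with an estimated correlation). They include the neutrophil enzymes npsn (3.90), mpx (3.72) and lyz (3.69) and the actin-binding coro1a (3.22). Blood stem cell and thrombocyte genes had 5 higher and 3 lower (5 and 4 adjusted over the list alone) of 16. The thrombospondin thbs1b (4.54), the clotting factor f13a1b (3.74) and the thrombopoietin receptor mpl, listed at 0 in both Fli1- libraries against 10.6 and 7.66 FPKM, were higher, and the transcriptional repressor gfi1b of blood cells was lower (-3.77). That list was not called (adjusted p = 0.179), with a median of -0.16, 0.54 under quantile normalization and 0.03 under median-ratio scaling, a mean of 0.13 and a test direction of higher. Here mpx, coro1a, thbs1b and hbbe2 were called whichever library was left out, and the other genes named lost their call without at least 1 library.

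Nervous system and eye genes were lower in High-Fli1+ than in Fli1- cells. Of 31 neuronal genes, 0 were higher and 27 lower (0 and 31 adjusted over the list alone) (median -4.0, adjusted p = 1.34e-15, adjusted p = 0.200 with an estimated correlation). The RNA-binding elavl3 went from 379 ± 14.5 to 10.7 ± 7.86 FPKM. Also lower were neurod4 (-4.80) and snap25b (-4.93). Neural progenitor and glia genes had 0 higher and 18 lower (0 and 22 adjusted over the list alone) of 28 (median -2.78, adjusted p = 1.92e-08, adjusted p = 0.0780 with an estimated correlation). Its largest falls were in the glutamate transporter slc1a2b (-4.71), pax6b (-4.22), sox2 at 36.6 and 46.1 against 0 and 1.36 FPKM, and sox1a listed at 0 in both High-Fli1+ libraries. Retina and lens genes had 0 higher and 14 lower (0 and 19 adjusted over the list alone) of 24 (median -2.75, adjusted p = 1.09e-07, adjusted p = 0.0780 with an estimated correlation). They include the photoreceptor factor crx (-4.56), vsx1 at 103 and 68.4 against 4.26 and 0 FPKM, rho at 78.2 and 38.7 against 1.84 and 0, and the crystallin crybb1, whose copies are hard to separate. Only neurod4 of these genes was called whichever library was left out. The rest lost it without at least 1.

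Other lineages changed less evenly. Liver, pancreas and gut genes had 0 higher and 20 lower (2 and 27 adjusted over the list alone) of 41 (median -2.28, adjusted p = 9.04e-07, adjusted p = 0.0780 with an estimated correlation). They include ins, the apolipoprotein apoa1b at 135 and 151 against 6.71 and 0 FPKM, the transferrin tfa (-5.09), and fabp2, listed at 0 in both High-Fli1+ libraries. Epidermis and periderm genes had 2 higher and 7 lower (2 and 11 adjusted over the list alone) of 30, with the adhesion molecules epcam (-4.44) and cdh1 (-4.26), atp1b1b and cldni lower. That list was not called (median -1.67, adjusted p = 0.151), unlike without High-Fli1+ replicate 1 (adjusted p = 0.0172). Notochord and hatching gland genes had 3 higher and 1 lower (3 and 2 adjusted over the list alone) of 8 (median 0.27, adjusted p = 0.137). Higher were the proteoglycan epyc (6.22), cd63 (1.68) and ucmaa, at 0 in Fli1- and 2.98 and 4.92 FPKM in High-Fli1+ libraries, and lower the hedgehog ligand shha (-2.85). Pigment cell genes had 0 higher and 2 lower (0 and 1 adjusted over the list alone) of 16, the lower ones being pax7a and trpm1b (median -0.14, adjusted p = 0.592). Their median was 0.45 under quantile normalization, their mean -0.35 and the test direction higher. Muscle genes gave 0 calls of 29 by limma and 3 at an unadjusted p under 0.05, all lower (median -0.09, adjusted p = 0.890). Their mean was -0.29, the test direction higher, and the median 0.28 under quantile normalization and 0 under median-ratio scaling. Every gene named in this group lost its call without at least 1 library.

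Among metabolic and stress lists, glycolysis had 0 higher and 9 lower (1 and 11 adjusted over the list alone) of 29 (median -1.37, adjusted p = 0.00173, adjusted p = 0.159 with an estimated correlation). Lower were aldocb (-3.39), pgam1b (-3.14), eno1a (-2.91) and gapdhs (-2.08). Oxidative phosphorylation had 0 higher and 3 lower of 46 (0 and 0 adjusted over the list alone, and 10 lower at an unadjusted p under 0.05). They are ppargc1a, a regulator of mitochondrial biogenesis (-3.60), ndufb8 and uqcrfs1. Its list call (median -0.65, adjusted p = 0.0186, adjusted p = 0.451 with an estimated correlation) was lost without Fli1- replicate 1 (adjusted p = 0.0523), without High-Fli1+ replicate 1 (0.371), under median-ratio scaling (0.0985) and without a variance trend (0.0527). Cell cycle genes were called as a list (median 0.19, adjusted p = 0.00469, adjusted p = 0.327 with an estimated correlation) with 0 of 38 members called by limma, 0 adjusted over the list alone and 3 higher at an unadjusted p under 0.05. Immediate early and dissociation stress genes had 14 higher and 1 lower (20 and 1 adjusted over the list alone) of 37 (median 0.99, adjusted p = 2.2e-08, adjusted p = 0.0896 with an estimated correlation). They include socs3b (2.66), ier2 (2.37), fosl1a and junba (2.01). No gene named in this group kept its call without each library in turn.

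Low-Fli1+ cells stood out from Fli1- cells mainly by myeloid, matrix and connective tissue transcripts. The neutrophil peroxidase mpx went from 0.745 ± 0.117 to 233 ± 26.7 FPKM (SD, n = 2), 134-fold (log2 fold change 7.06 ± 0.30 (SE), adjusted p = 0.00767), and the neutrophil protease npsn from 2.12 ± 0.933 to 291 ± 121 FPKM (91.6-fold). Other large rises were in the matrix proteases mmp9 (71.0-fold) and mmp13a (36.4-fold), lect2l (40.0-fold), coro1a (29.9-fold), lyz (27.0-fold), the leukocyte integrin itgb2 (26.0-fold), and fgfbp2b (31.2-fold). The matrix gene emilin3a stood at 0 and 1.36 FPKM in Fli1- and 132 and 327 in Low-Fli1+ libraries. The small nucleolar RNA SNORA3, lgals2b and s100t were listed at 0 in both Low-Fli1+ libraries, against 560.3 and 463, 87.2 and 64.4, and 36.4 and 22.2 FPKM in Fli1- libraries. Also among the 10 largest falls were pvalb5, at 0 in both, and krt91, hbz, lsm6, cldn7b, krt97 and ubxn4, at 0 in 1 Low-Fli1+ library and under 4 FPKM in the other. Keratin and globin copies are near-identical, so krt91, krt97 and hbz are uncertain.

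For Low-Fli1+ against Fli1-, limma called 622 of 19237 genes, 411 higher and 211 lower, 66.1% higher, against 50.1% with no filter on low values. With all libraries, the share ran from 48.5% without a variance trend to 78.2% with the replicate block. Lower calls outnumbered higher ones without Fli1- replicate 1, Fli1- replicate 2 or Low-Fli1+ replicate 2, so the balance of directions is not settled. The count was 0 without Low-Fli1+ replicate 1 (5483 at an unadjusted p under 0.05), without High-Fli1+ replicate 1 (3877), without High-Fli1+ replicate 2 (3859) and with only these populations in the fit (3875), and 238 with array weights. Leaving out genes at 0 in 1 library of a population and at 5 FPKM or more in the other, an alternative chosen after seeing the data, gave 1314. Of the 74 called genes named by the rule, 30, 34 and 49 remained called without Fli1- replicate 1, Fli1- replicate 2 and Low-Fli1+ replicate 2, and 0 without Low-Fli1+ replicate 1 or either High-Fli1+ library.

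Myeloid genes made the largest rise among the lists in Low-Fli1+ cells, 14 higher and 0 lower (20 and 0 adjusted over the list alone) of 25 (median 3.25, adjusted p = 1.98e-21, adjusted p = 0.0983 with an estimated correlation). Erythroid genes were lower as a list, 0 higher and 4 lower (1 and 15 adjusted over the list alone) of 20 (median -2.15, adjusted p = 1.32e-08, adjusted p = 0.0883 with an estimated correlation). Those called were hbae3 (-3.12), hbbe2 (-3.79), cahz (-2.34) and the spectrin sptb (-1.61). Blood stem cell and thrombocyte genes had 3 higher and 0 lower (7 and 5 adjusted over the list alone) of 16, the higher ones being f13a1b (3.25), thbs1b (2.07) and mpl, listed at 0 in both Fli1- libraries against 6.13 and 8.23 FPKM in Low-Fli1+. That list was not called (median -0.36, adjusted p = 0.228), with a mean of 0.09 and a test direction of higher. None of the gene calls in this group held without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2.

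Connective tissue lists followed the myeloid list. Mural and fibroblast-like genes had 17 higher and 0 lower (23 and 1 adjusted over the list alone) of 32 (median 2.81, adjusted p = 6.49e-19, adjusted p = 0.140 with an estimated correlation). They include foxc1b (3.91), cspg4 (3.78), pdgfra (3.70) and the pericyte receptor PDGFRB (3.51). Cartilage and bone genes had 15 higher and 0 lower (18 and 0 adjusted over the list alone) of 23 (median 2.71, adjusted p = 1.73e-19, adjusted p = 0.0896 with an estimated correlation). They include acana (4.17), col9a1a (3.80), col10a1a (3.66) and lect1, a cartilage-derived inhibitor of vessel growth (3.49). Basement membrane and matrix remodelling genes had 13 higher and 0 lower (21 and 1 adjusted over the list alone) of 32 (median 1.81, adjusted p = 5.90e-16, adjusted p = 0.157 with an estimated correlation). Their largest changes were in loxl2b (3.14), mmp2, mmp14a and serpinh1b (2.95). Neural crest and pharyngeal arch genes had 5 higher and 1 lower (11 and 1 adjusted over the list alone) of 29 (median 0.85, adjusted p = 0.000173, adjusted p = 0.0883 with an estimated correlation). The genes prrx1b (3.82), prrx1a (3.06) and twist1b (2.74) were higher, and dlx1a was listed at 0 in both Low-Fli1+ libraries against 11.2 and 9.88 FPKM in Fli1-. These gene calls were all lost without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2.

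Endothelial transcripts differed less between Low-Fli1+ and Fli1- cells, and 14 of the 29 endothelial core genes were listed at 0 in at least 1 Low-Fli1+ library. In that list 4 were higher and 0 lower (4 and 0 adjusted over the list alone) (median 0.08, adjusted p = 0.00708, adjusted p = 0.130 with an estimated correlation). They are fli1a, fli1b, the Src-family kinase yrk (3.0) and the vessel matrix gene mmrn2b (2.24). Angiogenic signalling genes had 4 higher and 0 lower (6 and 1 adjusted over the list alone) of 30 (median 0.20, 0.67 under quantile normalization and 0.16 under median-ratio scaling, adjusted p = 0.000530, adjusted p = 0.0896 with an estimated correlation). They are acvrl1 (2.66), klf2a (2.39), klf2b (2.01) and the BMP inhibitor smad6b (1.88). Venous and lymphatic genes were called as a list (median 0.26, adjusted p = 0.0104, adjusted p = 0.142 with an estimated correlation) with 0 of 18 members called by limma, 2 higher adjusted over the list alone and 6 higher at an unadjusted p under 0.05. That list call was lost without Low-Fli1+ replicate 1 (adjusted p = 0.0570). Arterial and Notch genes had notch2 higher (2.43) and 0 lower of 22 (4 and 1 adjusted over the list alone). The list was not called (median 0.11, adjusted p = 0.0830), but it was without Fli1- replicate 2 (adjusted p = 0.0460). The calls of these genes did not hold without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2.

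Liver, epidermal, neural and eye lists were lower in Low-Fli1+ than in Fli1- cells. Liver, pancreas and gut genes had 0 higher and 8 lower (1 and 23 adjusted over the list alone) of 41 (median -2.27, adjusted p = 2.03e-10, adjusted p = 0.0780 with an estimated correlation). Of them 34 were at 0 in at least 1 Low-Fli1+ library, and fabp1b.1, the hormone genes sst2 and gcga, and the digestive protease prss59.2 were at 0 in both. Epidermis and periderm genes had 1 higher and 3 lower (4 and 14 adjusted over the list alone) of 30 (median -1.95, adjusted p = 0.000236, adjusted p = 0.346 with an estimated correlation), with krt91, epcam and icn2 lower and krt8 higher (1.79). Neural progenitor and glia genes had 0 higher and 1 lower (0 and 6 adjusted over the list alone) of 28 (median -1.21, adjusted p = 8.27e-05, adjusted p = 0.0883 with an estimated correlation), the called one being the lipid carrier fabp7a (-1.96). Retina and lens genes had 0 higher and 1 lower (0 and 3 adjusted over the list alone) of 24 (median -1.27, adjusted p = 0.000288, adjusted p = 0.0983 with an estimated correlation), the called one being atoh7, at 4.12 and 8.21 FPKM in Fli1- and at 0 in both Low-Fli1+ libraries. Neuronal genes were called lower as a list (median -1.01, adjusted p = 0.000236, adjusted p = 0.460 with an estimated correlation) with 0 of 31 called by limma, 2 lower adjusted over the list alone and 9 lower at an unadjusted p under 0.05. The neuronal list call was lost without Low-Fli1+ replicate 2 (adjusted p = 0.0739). The gene calls were lost without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2.

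The remaining lists had at most 1 member called between Low-Fli1+ and Fli1- cells. Immediate early and dissociation stress genes had 1 higher and 0 lower (8 and 0 adjusted over the list alone) of 37 (median 0.67, adjusted p = 1.75e-06, adjusted p = 0.108 with an estimated correlation), the called one being ier2 (1.56). Oxidative phosphorylation had 0 higher and 1 lower (0 and 1 adjusted over the list alone) of 46, the lower one being uqcrb, at 0 in both Low-Fli1+ libraries against 22.8 and 18.2 FPKM. That list was called lower (median -0.67, adjusted p = 0.00246, adjusted p = 0.353 with an estimated correlation), and not without Low-Fli1+ replicate 1 (adjusted p = 0.0723). Glycolysis had 0 higher and 1 lower (1 and 3 adjusted over the list alone) of 29, the lower one being tpi1a, at 0 in both Low-Fli1+ libraries (median -0.76, adjusted p = 0.0591). The list was called with a pseudocount of 5 (0.0474), a mean FPKM of at least 2 (0.0459), quantile normalization (0.0300) and the replicate block (0.0365). Notochord and hatching gland genes had 1 higher and 0 lower (3 and 2 adjusted over the list alone) of 8, the higher one being epyc (median 0.09, adjusted p = 0.414). Pigment cell genes had 0 of 16 called by limma, and 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.39, adjusted p = 0.0845). The pigment list was called under quantile normalization (0.0227) and without Low-Fli1+ replicate 2 (0.0478). Muscle genes had 0 of 29 called by limma, and 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.18, adjusted p = 0.140). The muscle list was called without Fli1- replicate 2 (adjusted p = 0.0177), without Low-Fli1+ replicate 1 (0.000118) and under quantile normalization (0.0444). Cell cycle genes had 0 of 38 called by limma, and 1 higher and 7 lower at an unadjusted p under 0.05 (median -0.18, adjusted p = 0.895). The calls of ier2, uqcrb, tpi1a and epyc did not hold without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2.

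High-Fli1+ cells differed from Low-Fli1+ cells by more cartilage and endothelial transcripts and fewer red cell, neuronal, photoreceptor and myeloid ones. Cartilage matrix gene matn1 went from 66.7 ± 22.7 to 2823 ± 553 FPKM (SD, n = 2; log2 fold change 5.41 ± 0.52 (SE), adjusted p = 0.0134), and tnxba from 3.79 and 3.49 to 146 and 121 FPKM. The growth plate gene ucmab stood at 2.05 and 0 in Low-Fli1+ against 166 and 237 FPKM in High-Fli1+ libraries. The procollagen enhancer pcolceb, the cartilage-secreted mia, the arch factor dlx1a, the splicing gene snrpg, SNORA3 and SNORA35 were listed at 0 in both Low-Fli1+ libraries, and SNORD97 at 3.74 and 0. In High-Fli1+ libraries these ran from 30.1 and 26.3 FPKM for dlx1a to 1105 and 451 for SNORA3. Lower were the cone and bipolar cell transducin subunits gnb3a (78.9-fold, log2 fold change -6.30 ± 0.39 (SE), adjusted p = 0.00745) and gng13b (46.3-fold), the globins hbae3, hbbe1.1 and hbbe3, cahz (44.0-fold), alas2 (41.3-fold), the neuronal adhesion molecule dscaml1 (32.8-fold) and the synaptotagmin syt5b (31.5-fold). The retinal adhesion gene rs1a stood at 73.4 and 39.3 FPKM in Low-Fli1+ and at 0.300 and 0 in High-Fli1+ libraries.

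Between the positive populations limma called 1033 of 19237 genes, 234 higher and 799 lower in High-Fli1+, 22.7% higher, against 40.5% under median-ratio scaling, which moved the median log2 fold change of all genes from -0.13 to 0.09. The count was 2262 without Low-Fli1+ replicate 2, and 0 without Fli1- replicate 1 (3749 at an unadjusted p under 0.05), Fli1- replicate 2 (3737), Low-Fli1+ replicate 1 (5493), High-Fli1+ replicate 1 (3786) or High-Fli1+ replicate 2 (3396), and with only these populations in the fit (3686). It was 590 with no filter on low values, 366 with array weights, and 1819 without genes at 0 in 1 library of a population and at 5 FPKM or more in the other. Of the 72 called genes named by the rule, 64 remained called without Low-Fli1+ replicate 2, and 0 without any other library.

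Endothelial core genes had 6 higher and 0 lower (18 and 0 adjusted over the list alone) of 29 (median 2.11, adjusted p = 3.57e-13, adjusted p = 0.0780 with an estimated correlation). They include the plasmalemma vesicle gene vsg1, at 0 and 0.860 FPKM in Low-Fli1+ against 21.1 and 18.6 in High-Fli1+ libraries, tie1 (2.66), and the vessel genes rasip1 and clec14a, listed at 0 in both Low-Fli1+ libraries against 11.4 and 10.3 and 9.76 and 9.37 FPKM. Angiogenic signalling genes had 2 higher and 0 lower (4 and 0 adjusted over the list alone) of 30 (median 0.41, adjusted p = 0.00143, adjusted p = 0.0983 with an estimated correlation), namely klf2b (1.92) and klf2a (1.83). Venous and lymphatic genes had 2 higher and 1 lower (3 and 1 adjusted over the list alone) of 18 (median 0.58, adjusted p = 0.0104, adjusted p = 0.142 with an estimated correlation), with the scavenger receptors stab2 and mrc1a higher and prox1a lower (-3.13). That list call was lost without Low-Fli1+ replicate 2 (adjusted p = 0.0683) and at a mean FPKM of at least 2 (0.161). Arterial and Notch genes were called as a list (median 0.52, adjusted p = 0.0353, adjusted p = 0.249 with an estimated correlation) with 0 of 22 called by limma, 2 and 2 adjusted over the list alone, and 5 higher and 3 lower at an unadjusted p under 0.05. Their list call was lost without Low-Fli1+ replicate 1 (0.0647), Low-Fli1+ replicate 2 (0.0686), High-Fli1+ replicate 1 (0.0572) or High-Fli1+ replicate 2 (0.0762), without a variance trend (0.0582), and without genes at 0 in 1 library of a population and at 5 or more in the other (0.0630). All gene calls in this group were lost without each library other than Low-Fli1+ replicate 2 in turn.

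Cartilage and bone genes had 13 higher and 0 lower (20 and 0 adjusted over the list alone) of 23 (median 2.57, adjusted p = 2.97e-20, adjusted p = 0.0896 with an estimated correlation). They include ucmab, matn1, col11a2 (3.86) and acanb (3.61). Neural crest and pharyngeal arch genes had 4 higher and 2 lower (15 and 2 adjusted over the list alone) of 29 (median 1.47, adjusted p = 6.34e-09, adjusted p = 0.0780 with an estimated correlation). The 4 largest were dlx1a, dlx3b, dlx4a (3.92) and gsc (2.91), all higher. Mural and fibroblast-like genes had 0 of 32 called by limma, 6 higher adjusted over the list alone and 10 higher and 1 lower at an unadjusted p under 0.05, and were called as a list (median 0.43, adjusted p = 0.00133, adjusted p = 0.451 with an estimated correlation). Basement membrane genes were likewise called as a list (median 0.49, adjusted p = 0.000146, adjusted p = 0.382 with an estimated correlation) with 0 of 32 called by limma, 0 adjusted over the list alone, and 9 higher and 1 lower at an unadjusted p under 0.05. Notochord and hatching gland genes had 2 higher and 0 lower (2 and 0 adjusted over the list alone) of 8, epyc (2.79) and ucmaa (median 0.09, adjusted p = 0.210). The gene calls in this group were lost without each library other than Low-Fli1+ replicate 2 in turn.

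Myeloid and erythroid genes were lower in High-Fli1+ than in Low-Fli1+ cells. Myeloid genes had 0 higher and 9 lower (0 and 14 adjusted over the list alone) of 25 (median -1.68, adjusted p = 1.00e-08, adjusted p = 0.200 with an estimated correlation). They include mmp9 (-3.82), mpx (-3.34), and the macrophage genes mpeg1.1 (-3.61) and csf1ra (-3.17). Erythroid genes had 0 higher and 12 lower (0 and 17 adjusted over the list alone) of 20 (median -3.0, adjusted p = 1.95e-12, adjusted p = 0.0780 with an estimated correlation). Blood stem cell and thrombocyte genes had thbs1b higher (2.47) and 0 lower of 16 (2 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.428). Neuronal genes had 0 higher and 19 lower (0 and 27 adjusted over the list alone) of 31 (median -2.94, adjusted p = 7.73e-16, adjusted p = 0.200 with an estimated correlation). They include neurod4 (-4.70), elavl3 (-4.59) and isl1 (-3.87). Neural progenitor and glia genes had 0 higher and 8 lower (1 and 15 adjusted over the list alone) of 28 (median -1.39, adjusted p = 1.04e-05, adjusted p = 0.0780 with an estimated correlation). They include pax6b (-4.07), pax6a (-3.69), sox2 and id4. Retina and lens genes had 0 higher and 5 lower (0 and 9 adjusted over the list alone) of 24 (median -1.53, adjusted p = 0.000734, adjusted p = 0.108 with an estimated correlation). They include vsx1, crx (-4.59), rho and the photoreceptor factor nr2e3, at 16 and 10.1 FPKM in Low-Fli1+ and 0 in both High-Fli1+ libraries. The gene calls named here were lost without each library other than Low-Fli1+ replicate 2 in turn.

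The other lists gave few calls between the positive populations. Glycolysis had 0 higher and 4 lower (1 and 6 adjusted over the list alone) of 29 (median -0.64, adjusted p = 0.0326, adjusted p = 0.271 with an estimated correlation), the lower ones being aldocb, pgam1b, eno1a and pkma. Its list call was lost without Low-Fli1+ replicate 2 (adjusted p = 0.269) and without a variance trend (0.0716). Epidermis and periderm genes had krt8 higher (1.44) and 0 lower of 30 (1 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.0212, adjusted p = 0.502 with an estimated correlation). That list call was lost without Low-Fli1+ replicate 2 (0.436), without High-Fli1+ replicate 1 (0.299), at a mean FPKM of at least 2 (0.0708), and under quantile (0.113) and median-ratio (0.0798) scaling. Cell cycle genes had the thymidylate synthase gene tyms higher (1.64) and 0 lower of 38 (1 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.00127, adjusted p = 0.286 with an estimated correlation). Immediate early and dissociation stress genes had 0 of 37 called by limma, 0 adjusted over the list alone, and 6 higher and 3 lower at an unadjusted p under 0.05. That list was called (median 0.42, adjusted p = 0.00264, adjusted p = 0.205 with an estimated correlation), and not under quantile normalization (0.219). Liver, pancreas and gut genes had 1 higher and 2 lower (1 and 2 adjusted over the list alone) of 41, with the gut factor foxa3 higher and the apolipoproteins apoa1a and apoc1 lower (median 0, mean -0.26, test direction higher, adjusted p = 0.749). Oxidative phosphorylation had uqcrb higher and 0 lower of 46 (1 and 0 adjusted over the list alone; median -0.20, adjusted p = 0.814), with a mean of 0.06, a test direction of higher and a median of 0.13 under median-ratio scaling. Pigment cell genes had 0 of 16 called by limma and 3 lower at an unadjusted p under 0.05 (median -0.84, adjusted p = 0.247). Muscle genes had 0 of 29 called by limma and 7 lower at an unadjusted p under 0.05 (median -0.25, adjusted p = 0.367), and the muscle list was called without Low-Fli1+ replicate 1 (adjusted p = 0.00222). The gene calls were lost without each library other than Low-Fli1+ replicate 2 in turn.

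**Figure D3:**
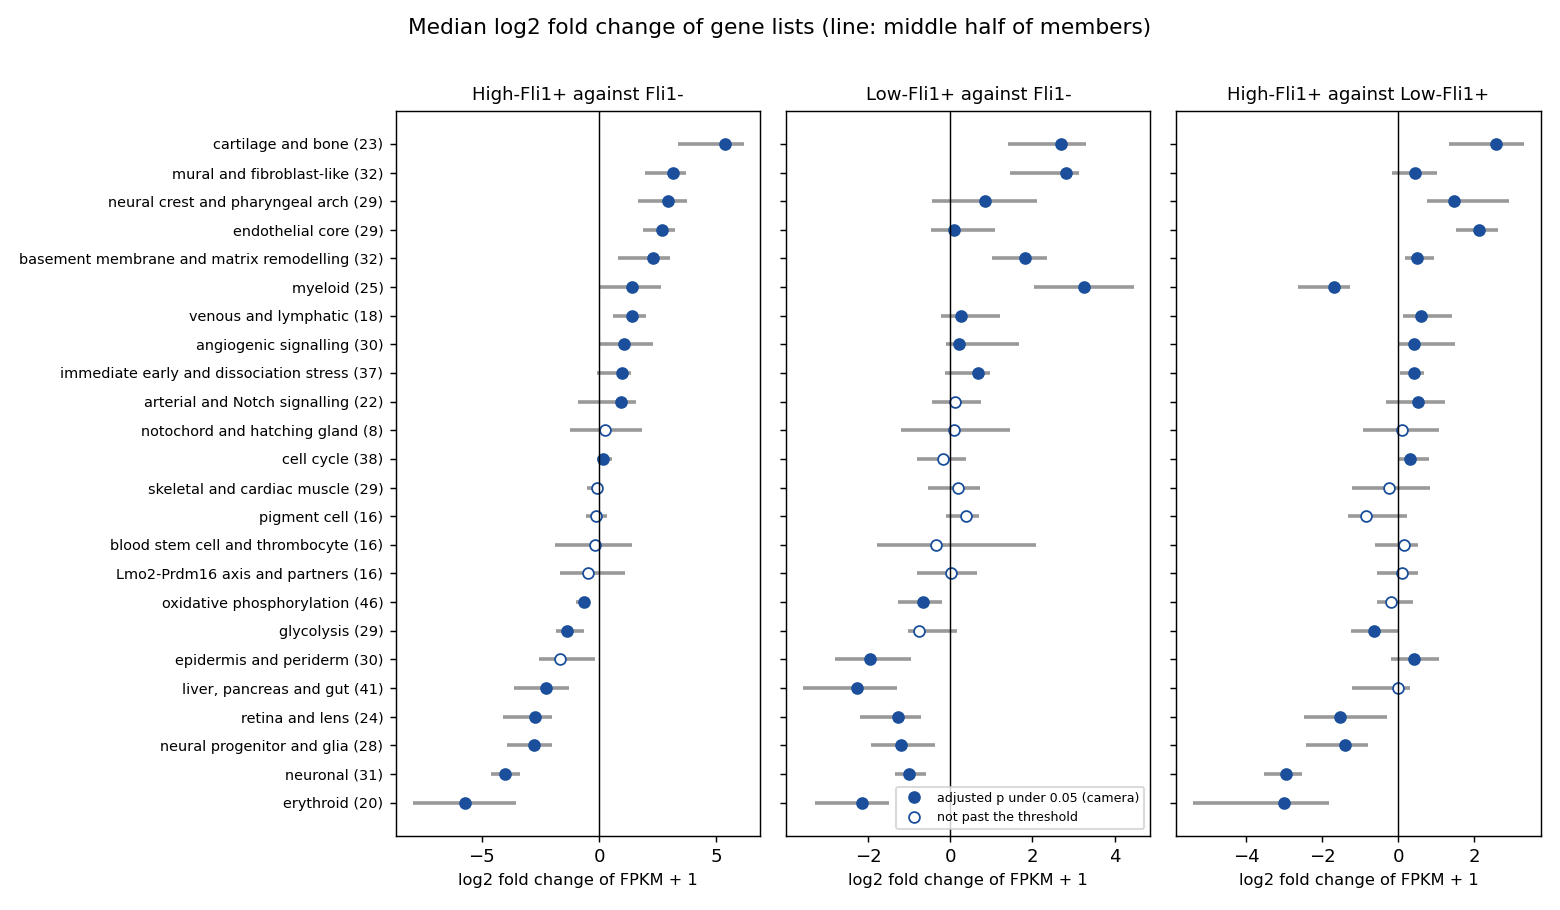
For each gene list (y axis, with the number of genes tested), points give the median log2 fold change of FPKM + 1 (x axis) in each of the 3 comparisons, lines its members' interquartile range, and filled points an adjusted p under 0.05 by camera. Cartilage and bone had the highest median in High-Fli1+ against Fli1- cells, 5.38, and myeloid the highest in Low-Fli1+ against Fli1-, 3.25.

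Across the 3 populations limma's moderated F test called 2804 genes. By the pairwise calls, 697 genes were lower in High-Fli1+ than in both other populations and 133 higher, while 30 were higher in Low-Fli1+ than in both others and 42 lower. The genes highest in Low-Fli1+ include myeloid ones, mmp9, mpx, npsn, csf1ra and the leukocyte actin regulator NCKAP1L, and the chemokine receptors ccr12a, at 0 in the other 4 libraries, and ccr9b. The others named by the rule are rgs14a, the T cell kinase prkcq and myom1b. Both positive populations were higher than Fli1- for 348 genes and lower for 142, against 23.8 and 24.2 expected of independent lists and 0 and 0 in 20 simulations of unchanged groups against the same Fli1- libraries. Those simulations made at most 1 call in a comparison, so their overlap of 0 sets no level for real changes. Opposite calls were found for 0 genes. Shared calls were 308 higher and 315 lower with no filter on low values, and 236 and 41 with the replicate block. Without either Fli1- library, most shared calls were lower. Across genes, the log2 fold changes of the 2 comparisons had r of 0.576, against 0.503 simulated, and a covariance of 1.05 against 0.264, a difference of 0.789. With 1 Fli1- library serving each comparison and none shared, the covariance was 0.874 and 0.979 (r of 0.439 and 0.508) for the 2 ways to assign them. The calls were not split in this way, so part of their excess overlap may come from the shared controls. The F test gave 604 without Fli1- replicate 1, 655 without Fli1- replicate 2, 4336 and 5262 without Low-Fli1+ replicates 1 and 2, and 0 without High-Fli1+ replicate 1 or 2 (5290 and 5004 at an unadjusted p under 0.05). Array weights gave 4442 genes. The overlap of 490 genes was 0 without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or High-Fli1+ replicate 2, and 209 with array weights. Without each of the 6 libraries in turn, no gene called with all of them changed direction in any of the 3 comparisons. This had to follow, because for every called gene both libraries of 1 population lay above both of the other.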

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

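The tests of short transcripts, of 1 mixing ratio and of a population with myeloid transcripts were chosen only after the results were seen. Low-Fli1+ stood outside the span of the other populations in 3 results, each tested directly between High-Fli1+ and Low-Fli1+. The median log2 difference of the myeloid list was -1.68 (adjusted p = 1.00e-08, adjusted p = 0.200 with an estimated correlation), against a rise over Fli1- in both positive populations (adjusted p = 0.218 for High-Fli1+ and 0.0983 for Low-Fli1+ with an estimated correlation). By limma 30 genes were higher in Low-Fli1+ than in both others, and 42 were lower. Calls between the positive populations were lost without each library other than Low-Fli1+ replicate 2 in turn. Leaving out a Fli1- library changes no fold change there, only the estimate of the spread.

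Genes at 0 in Low-Fli1+ libraries include abundant ones. Of 7009 genes at 5 FPKM or more in the 4 other libraries, 230 were at 0 in Low-Fli1+ replicate 1 and 60 in replicate 2. Among the 701 genes with the highest levels (median 144 FPKM), 2.28% were at 0 in replicate 1 and 0.285% in replicate 2. Lower expression in Low-Fli1+ cells is argued against as the main source: in the Low-Fli1+ library where they were not selected, these genes lay at a median log2 difference of -0.23 (95% interval -0.46 to -0.08; 290 values, of which 42 from genes at 0 in both are at 0) from the other libraries, where a real loss would give at least 1 lower. For the 21 genes at 0 in both, taken alone, lower expression stays open. Loss of short transcripts may contribute, since 13.7% of 146 genes in 3 short-transcript classes were at 0, 5.55 times the share of other genes matched on level (95% interval 3.39 to 8.57). Fewer distinct fragments stay open. Zeros of the Low-Fli1+ libraries coincided in those 21 genes where 2.78 were expected within bins of level, a ratio of 7.56 (4.68 to 11.6), beyond the bound of 1.5 set beforehand. That bound was wrong, because at equal FPKM a short transcript has fewer fragments, so the same genes would be lost in both libraries. A call that rests on a gene at 0 in both Low-Fli1+ libraries, as for SNORA3, snrpg, dlx1a and uqcrb, may therefore come from the library or from the cells.

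Low-Fli1+ levels were also set against the idea that this population holds Fli1- and High-Fli1+ cells in 1 ratio. The position of Low-Fli1+ between Fli1- (0) and High-Fli1+ (1), on the FPKM scale, would then be alike in all lists with 8 or more called members. The list medians ran from 0.125 for endothelial core genes (95% interval 0 to 0.172) to 3.82 for myeloid genes (2.48 to 7.50), a difference of 3.70. This argues against a single ratio, though the myeloid value restates the pattern that prompted the test. The other lists ran up to 1 (liver, pancreas and gut). Intervals over genes that share 2 libraries may be too narrow. A population of its own with myeloid transcripts stays open: 68% of 25 myeloid genes (46.5% to 85.1%) were higher in both Low-Fli1+ libraries than in the 4 others, against 8.60% of all genes tested, but this share restates the pattern that prompted it. Among the most abundant of them, npsn stood at 206 and 377 FPKM and mpx at 214 and 251 in Low-Fli1+ libraries. As reporter expression is known from some blood cells, myeloid cells with a weak reporter are a candidate source, but other cells carried along are as well, and the labels name no gate that would remove them.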

How the results depend on the processing

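The alternative without genes at 0 in 1 library was chosen only after the data were seen. Of the named genes' values under all alternatives, 2907 kept direction and side of the threshold, 1323 kept direction without passing, 6 passed newly and 2 changed sign, both of lmo2 between the positive populations, where it was not called. With pseudocounts of 0.1 and 5, a mean FPKM of at least 2, quantile normalization, median-ratio scaling and no variance trend, the gene counts, the overlap and the number of lists stayed within 1.5 times the values reported. The lists depend on the correlation assumed between genes: 51 of 72 were called at 0.01, and 0 by camera with the estimated correlation (27 at an unadjusted p under 0.05). They numbered 47 to 53 without 1 library. Fry, which asks whether a list's genes move 1 way without comparing them with other genes, gave an adjusted p under 0.05 for 39 of the 51 and for 3 others. The 12 it did not pass are cell cycle (adjusted p = 0.345) and oxidative phosphorylation (0.0813) in High-Fli1+ against Fli1-; neural crest (0.0583), neuronal (0.163), epidermis (0.0506) and oxidative phosphorylation (0.0832) in Low-Fli1+ against Fli1-; and mural (0.234), basement membrane (0.207), epidermis (0.420), cell cycle (0.106), glycolysis (0.0582) and immediate early (0.0997) between the positive populations. The 3 others are arterial and Notch (0.0131) and glycolysis (0.0407) in Low-Fli1+ against Fli1-, and pigment cell (0.0278) between the positive populations.

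Between High-Fli1+ and Low-Fli1+ the count was 590 with no filter on low values, where more genes enter the adjustment. With only the populations compared, limma called 0 genes in Low-Fli1+ against Fli1- and 0 in High-Fli1+ against Low-Fli1+ (3875 and 3686 at an unadjusted p under 0.05), while High-Fli1+ against Fli1- gave 4968; the cause was not tested. Array weights, which gave Low-Fli1+ 0.438 on average against 2.01 for Fli1- and 1.13 for High-Fli1+, gave 5659 in High-Fli1+ against Fli1-, 238 in Low-Fli1+ against Fli1-, 366 in High-Fli1+ against Low-Fli1+, 4442 by the F test and an overlap of 209; the cause was not tested. Without genes at 0 in 1 library and at 5 or more in the other, Low-Fli1+ against Fli1- gave 1314, High-Fli1+ against Low-Fli1+ 1819 and the overlap 952, where fewer genes are tested and those with the widest spread are left out.

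With the replicate block, Low-Fli1+ against Fli1- gave 335 genes and an overlap of 277, and fli1b in Low-Fli1+ a log2 fold change of 3.69 that did not pass (adjusted p = 0.0640). Libraries of the same number deviated together only weakly, and the numbers are not taken to pair them: r between their deviations across genes was 0.0962 for Fli1- and Low-Fli1+, 0.0806 for Fli1- and High-Fli1+ and 0.121 for Low-Fli1+ and High-Fli1+. In Low-Fli1+ against Fli1- the block also made calls of the glycolysis (median -0.76, adjusted p = 0.0365) and arterial and Notch (0.11, adjusted p = 0.0488) lists. The cause was not tested.

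For the title and reporter genes the calls changed as follows, and the cause was not tested. With a pseudocount of 5, fli1b did not pass in High-Fli1+ (1.37, adjusted p = 0.0606) or Low-Fli1+ (1.87, 0.0633) against Fli1-, and fli1a passed between the positive populations (1.78, 0.0437). PRDM16 between the positive populations stayed at 1.64 and did not pass without a variance trend (0.0537), with only the populations compared (0.143) or with array weights (0.0579). With only the populations compared, fli1a (4.03, 0.104) and fli1b (3.69, 0.107) did not pass in Low-Fli1+, and lmo2 passed in High-Fli1+ against Fli1- (-2.08, 0.0420). With array weights fli1a in Low-Fli1+ did not pass (4.03, 0.0793) and lmo2 passed in High-Fli1+ against Fli1- (-2.08, 0.0363). PRDM16 in Low-Fli1+ against Fli1- passed without genes at 0 in 1 library (1.12, 0.0433). Over the alternatives other than leaving out a library, adjusted p ran from 0.000461 to 0.0110 for PRDM16, 0.000927 to 0.0134 for fli1a, 0.00308 to 0.0606 for fli1b and 0.0363 to 0.427 for lmo2 in High-Fli1+ against Fli1-. In Low-Fli1+ against Fli1- it ran from 0.0137 to 0.104 for fli1a, 0.0177 to 0.107 for fli1b and 0.0433 to 0.132 for PRDM16, and from 0.0138 to 0.143 for PRDM16 between the positive populations.

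Without 1 library, the lone library of its population is assumed to vary like the others, and the spread rests on fewer libraries. In High-Fli1+ against Fli1- the count ran from 201 without High-Fli1+ replicate 2 to 4906 without Low-Fli1+ replicate 2, and the log2 fold changes from 5.05 to 6.73 for fli1a (adjusted p = 0.0130 to 0.0612), 2.89 to 3.21 for fli1b (0.0139 to 0.172) and -2.56 to -1.61 for lmo2 (0.0411 to 0.526). In Low-Fli1+ against Fli1- it ran from 0 by limma without Low-Fli1+ replicate 1, High-Fli1+ replicate 1 or 2 (5483, 3877 and 3859 at an unadjusted p under 0.05) to 797 without Low-Fli1+ replicate 2, with 3.19 to 4.88 for fli1a (0.0167 to 0.102), 3.05 to 4.33 for fli1b (0.0467 to 0.200) and -3.68 to -1.28 for lmo2 (0.0537 to 0.623). Between the positive populations it ran from 0 by limma for 5 of the 6 libraries to 2262 without Low-Fli1+ replicate 2, with 1.57 to 1.70 for PRDM16 (0.0371 to 0.139), -0.81 to 1.59 for lmo2 and -1.28 to -0.0040 for fli1b. The count of the F test over the 3 populations ran from 0 by limma without High-Fli1+ replicate 1 or 2 (5290 and 5004 at an unadjusted p under 0.05) to 5262, and the overlap from 0 to 606.

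Camera's direction turned only for lists that passed neither as reported nor under the alternative. Their medians, which can differ in sign from camera, were as follows. Muscle in High-Fli1+ against Fli1- stood at -0.41 with a pseudocount of 0.1, 0 under median-ratio scaling and -0.095 without genes at 0 in 1 library. Cell cycle in Low-Fli1+ against Fli1- stood at -0.18 with a pseudocount of 0.1, with no filter on low values and with only the populations compared. Between the positive populations, oxidative phosphorylation stood at -0.13 with no filter, -0.20 with only the populations compared and -0.33 without genes at 0 in 1 library, muscle at 0.14 at a mean FPKM of at least 2, and liver, pancreas and gut at -0.89 at that mean, -0.13 under quantile normalization and 0 under median-ratio scaling. Without 1 library the medians ran from -0.61 to 0.19 for muscle in High-Fli1+ against Fli1-, and in Low-Fli1+ against Fli1- from -0.45 to 0.99 for muscle, -0.79 to 0.48 for notochord and hatching gland and -0.25 to -0.013 for cell cycle. Between the positive populations they ran from -1.16 to 0 for muscle and -0.35 to 0.093 for oxidative phosphorylation. The cause was not tested.

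An alternative restricted to genes with a good quantification status was not run, because the table holds no status. Depth is unknown, so no limit on detection can be set per library.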

Other observations

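The 10 gene families tested here were chosen only after the results were seen, and the PRDM16 tests before. By camera 15 of their 30 tests were called, and 0 with an estimated correlation. Collagen genes were higher in both positive populations. In High-Fli1+ against Fli1- cells 26 of 50 were higher and 1 lower (median log2 fold change 2.31, 2.55 under quantile normalization and 2.62 under median-ratio scaling, adjusted p = 4.22e-16 by camera, adjusted p = 0.498 with an estimated correlation). In Low-Fli1+ against Fli1- 22 were higher and 0 lower (median 1.89, adjusted p = 2.00e-12, adjusted p = 0.498 with an estimated correlation), and between the positive populations 10 were higher in High-Fli1+ (median 0.63, adjusted p = 1.36e-07, adjusted p = 0.505 with an estimated correlation). The distal-less genes, which pattern the pharyngeal arches, were higher in High-Fli1+ than in Low-Fli1+ cells. Of 8, dlx1a, dlx3b, dlx4a and dlx4b were called (median 3.27, 3.32 under quantile normalization and 3.49 under median-ratio scaling, adjusted p = 2.81e-06, adjusted p = 0.498 with an estimated correlation).

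Hox genes, which set position along the body axis, were lower in High-Fli1+ than in Fli1- cells, with 0 of 47 higher and 11 lower (median -1.70, -1.31 and -1.48 under the scalings, adjusted p = 0.00771, adjusted p = 0.505 with an estimated correlation). Against Low-Fli1+, hoxb13a, hoxc3a, hoxc6a and hoxc8a were lower (median -0.97, adjusted p = 0.0196, adjusted p = 0.532 with an estimated correlation). Protocadherins, adhesion genes abundant in neurons, had 25 of 62 lower and 3 higher in High-Fli1+ against Fli1- cells (median -1.86, -1.49 and -1.63 under the scalings, adjusted p = 1.51e-05, adjusted p = 0.505 with an estimated correlation), the 3 higher being pcdh12, pcdh18a and pcdh18b. Against Low-Fli1+ 9 were lower and 0 higher (median -1.38, adjusted p = 2.03e-06, adjusted p = 0.505 with an estimated correlation). Gene calls between the positive populations were lost without each library other than Low-Fli1+ replicate 2 in turn.

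In the other called families few or no genes passed. Small nucleolar and nuclear RNAs were called lower in Low-Fli1+ than in Fli1- libraries, with 0 of 31 higher and 2 lower (median -2.61, -2.34 and -2.54 under the scalings, adjusted p = 0.00155, adjusted p = 0.498 with an estimated correlation). High-Fli1+ against Fli1- had a similar median of -2.33 but was not called (1 higher, 2 lower, adjusted p = 0.769). High-Fli1+ against Low-Fli1+ was called higher, with 3 higher and 0 lower (median 0.12, -0.13 and 0.24 under the scalings, adjusted p = 0.00771, adjusted p = 0.498 with an estimated correlation). Loss in the library, as for SNORA3 above, stays open. Distal-less genes were also higher in High-Fli1+ than in Fli1- cells, 2 of 8 (adjusted p = 0.00134, adjusted p = 0.505 with an estimated correlation). Cytosolic ribosomal protein genes (0 of 90 called) and mitochondrial genome genes (0 of 13) were called higher as families in High-Fli1+ against Fli1- (medians 0.24 and 0.48, adjusted p = 0.00771 for both) and against Low-Fli1+ (medians 0.56 and 0.45, adjusted p = 0.000131 and 0.00771). Under quantile normalization the mitochondrial median against Low-Fli1+ was -0.042. Fox, tbx and solute carrier families were not called.

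PRDM16 was higher in High-Fli1+ than in Fli1- cells, and scaling of the FPKM columns is argued against as its source. The lower log2 fold change under quantile and median-ratio scaling was 2.82. More endothelial and more cartilage cells in High-Fli1+ both stay open: the position of PRDM16 in Low-Fli1+ between Fli1- (0) and High-Fli1+ (1) was 0.203, inside the 5th to 95th percentile of called endothelial core members (-0.0667 to 1.14), of called cartilage and bone members (0.0198 to 0.429) and of called neural crest and pharyngeal arch members (0.0601 to 0.736). These cannot be told apart here, because the ranges overlap and cell numbers were not measured. The position lay below the range of called mural members (0.255 to 1.89) and of basement membrane members (0.370 to 0.769), with 1 member lower in each. Regulation of prdm16 within a cell type was not tested, and neither was an effect of lmo2, since no library has either gene altered.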
